A study of Oryza sativa Japonica Group with 18 samples.

How the data were processed

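RNA was measured in whole roots of rice seedlings, in 18 libraries of polyA RNA with randomly primed and amplified cDNA per the labels. The 6 groups combine 2 genotypes (Kitaake wild type and the php1,2,3 mutant) with control medium, 100 nM BA or 5 µM BA, and each holds 3 biological replicates of 8 seedlings per the labels. Shoot tissue, which the labels also name, was not analysed here.

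The authors deposited 1 table per library with 44682 transcripts. Per the file headers each transcript has a length, an effective length, a TPM value and an expected (estimated) read count, the columns that salmon writes. The effective length and TPM were deposited as other and TPM values and were used here for length offsets alone. The submitters' processing notes name the build IRGSP-1.0 and DESeq2. The counting tool and its version, read trimming, the use of strand and the annotation release are not given in the sources used here. Of the deposited expected counts 38.3% were not whole numbers, and after summing transcripts to 37862 genes 23.5% of the sums were not. Sums were rounded before testing. For 5355 genes more than 1 transcript was summed, and 3803 genes had no count in any library. Expected counts divide reads among near-identical transcripts, so values of close copies (RR9 and RR10, the neighbouring aquaporins PIP2-4 and PIP2-5, RBCS genes) are uncertain. Without strand information, reads of overlapping and antisense genes cannot be told apart.

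Gene names came from lists written by hand, pairing 266 gene identifiers with published symbols. The reference table given with the files (assembly ASM3414082v1) holds locus names without products for rice, and served to check these pairs: 189 were in the table, 185 lay on the same chromosome, 182 also in the place that the order of identifiers gives within 3 Mb, and 4 names were dropped. Of 28 gene lists fixed before the data were examined 24 were used. For 12 of these (PHP, type-A and type-B response regulators, cytokinin receptors and phosphotransfer proteins, cytokinin oxidases, cytokinin synthesis, nitrogen, iron, diterpenoid phytoalexins, circadian clock, crown root and meristem, root hair) member identifiers were fixed then too. For 12 (photosynthesis, Aux/IAA, auxin transport, aquaporins, expansins, ethylene synthesis, gibberellin oxidases, jasmonate, WRKY, heat shock, chitinases and pathogenesis-related proteins, cell cycle and histones) products were fixed, and the members were written down before any value was read. The remaining 4 lists (auxin-induced SAUR and GH3 genes, class III peroxidases, ribosomal proteins and glutathione transferases) were not analysed here. Photosynthesis genes also stand for shoot or green tissue that a root sample could hold.

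Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr, which left 27607 genes with 99.94% of the counts, and libraries were scaled by TMM (factors between 0.966 and 1.03). One edgeR quasi-likelihood fit with robust dispersion covered all 18 libraries with 1 coefficient per group. Every contrast, including the genotype by BA interactions, was tested in it with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05, and an edgeR adjusted p in the text is this one. The SE is the log2 fold change divided by the square root of the F statistic. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 264 tests (24 lists in 11 comparisons). Of these 78 were called, and 17 remained with an estimated correlation. Where the text gives a pair of p-values after a list's median, the first is the camera adjusted p and the second is the adjusted p with an estimated correlation. Members were counted over all genes tested and adjusted over the list alone.

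Named genes were those with a name, an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and libraries of the 2 groups that did not overlap (not required for interactions). The 8 largest rises and 8 largest falls were taken, and up to 3 further members of each list with a call. Chance gives no overlap of 3 against 3 libraries in 10% of unchanged genes. The PHP genes were added to every comparison. Genes with no name are given for 1 comparison.

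Totals ranged from 12959984 to 24069828 estimated counts, so that 3 counts, the floor used here, correspond to between 0.1246 and 0.2315 CPM per library. Reads without molecular identifiers are not independent molecules, and floors cover counting error alone. No pair of libraries of a group agreed within sampling noise (chi-square per degree of freedom between 9.37 and 64.5), and none was merged. The procedure was tested on simulated counts for 27607 genes in the design of php against WT on control medium: it recovered 47 of 104 genes changed 2-fold (45.2%) and 83 of 96 changed 4-fold (86.5%) and 6 of 8 genes of a list raised 3-fold, with 7 unchanged genes among those called (143), and called 0 genes in a comparison simulated without change. The genes changed 2-fold or 4-fold were drawn above a minimum mean CPM. Each gene was simulated independently, with the same dispersion in all groups and no variation shared among genes within a group. The real libraries may therefore give poorer rates.

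Whether the replicate numbers pair libraries across groups was checked by correlating deviations from the group means for each pair of groups, with pairing taken where all 3 correlations were over 0.1. This held for 1 of 15 pairs of groups, php with 100 nM and php with 5 µM BA. Alternatives fixed before the data were examined were DESeq2's size factors in edgeR, no scaling factors, no filter, a stricter filter (5 CPM in 3 libraries), DESeq2 1.42.0, a fit of the compared groups alone, the replicate number as a block, transcript length offsets, a fold minimum of 1.5 (glmTreat), leaving out each library, and for lists an estimated correlation and fry. Leaving out 4 php libraries (replicate 3 in each medium and control replicate 2), picked by their place on the within-group component, summing RR9 and RR10, and correlating over genes called in php were chosen after seeing the data.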

Results

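Whole roots of rice seedlings (Oryza sativa, Japonica group, cultivar Kitaake) were profiled by RNA sequencing in 6 groups of 3 libraries, 18 libraries in all. Kitaake served as the wild type (WT), and the second genotype, called php here, was labelled as a php1,2,3 loss-of-function mutant. Pseudo-phosphotransfer proteins resemble the proteins that relay phosphate from cytokinin receptors to response regulators but lack the histidine that carries it. Roots of each genotype came from control medium or from treatment with the synthetic cytokinin benzyl adenine (BA) at 100 nM or 5 µM. The labels call the replicates biological, each a pool of 8 seedlings. The libraries held 22747993, 18385108 and 17746002 estimated counts in WT control, 23252638, 20474961 and 13862491 in WT with 100 nM BA, and 16960229, 21871365 and 18648388 in WT with 5 µM BA. The php libraries held 18212119, 24069828 and 15492999 on control medium, 21201114, 17327192 and 12959984 with 100 nM BA, and 17357342, 18528488 and 18435664 with 5 µM BA. Between 29554 and 31064 genes had a count in each library, and 27607 genes were tested. Changes below are log2 fold changes ± SE from edgeR over 3 libraries per group. Levels are CPM, counts scaled to the library total, ± SD with n = 3.

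The 3 targeted genes were examined first. PHP1 (Os01g0743800) lay between 2.54 and 4.95 CPM in the 9 WT libraries and between 8.4 and 17.1 CPM in the 9 php libraries. Its difference was 1.43 ± 0.29 on control medium (edgeR adjusted p = 0.052), 1.43 ± 0.30 with 100 nM BA (edgeR adjusted p = 0.18) and 1.62 ± 0.30 with 5 µM BA (edgeR adjusted p = 0.023). On control medium DESeq2 called it (adjusted p = 8.1e-04), as did edgeR without php control replicate 2 (adjusted p = 0.029). With 5 µM BA its call was lost without WT replicate 1, 2 or 3 or php replicate 3 of that medium, with adjusted p up to 0.15. PHP2 (Os05g0186100) had between 2 and 19 counts per library and stayed at or below 1.08 CPM. Its differences (0.33 ± 0.68, 0.05 ± 0.68 and 0.82 ± 0.66) were not called. PHP3 (Os05g0521300) lay between 31.7 and 46.2 CPM in WT and between 30 and 46.1 CPM in php, with uncalled differences of -0.09, 0.13 and -0.02, each ± 0.10. The kind of lesion is not given in the sources used here, so these levels do not check the genotype labels.

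Libraries also differed within groups. The first component of deviations from the group means held 28.5% of that variance. It placed php control replicate 2 at 73.6. Replicate 3 of php lay at -60.7 on control medium, -46.3 with 100 nM BA and -75.4 with 5 µM BA, while WT libraries lay between -25.5 and 35.1. These are the 4 php libraries left out in some fits below, but php replicate 2 with 100 nM BA (39.4) and with 5 µM BA (49.0) also lay outside the WT range. The component followed the replicate number in both genotypes, with replicate 2 highest in 6 of 6 groups and replicate 3 lowest in 5 of 6. The mean effective transcript length, weighted by reads, was 1366, 1392 and 1379 bases in those replicate 3 libraries and 1543 bases in php control replicate 2. It lay between 1418 and 1463 bases in the remaining php libraries and between 1444 and 1517 bases in WT. Lower values thus also went with the php genotype. Across libraries, the median member of the diterpenoid phytoalexin (r = 0.93), iron uptake (0.88), photosynthesis (0.87), jasmonate (0.83), chitinase and pathogenesis-related (0.83), nitrogen (0.76), ethylene (0.60) and WRKY (0.55) lists moved with this component. The corresponding values were -0.35 for type-A response regulators, -0.30 for cytokinin oxidases, 0.36 for aquaporins, 0.14 for expansins and -0.74 for auxin transport.

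The first comparison asks how php roots differed from WT roots without added cytokinin. Type-A response regulators, cytokinin-induced genes that act as negative feedback on the pathway, were higher in php. RR10 (Os12g0139400) went from 10.2 ± 0.671 CPM in WT to 67.7 ± 9.05 CPM in php (2.74 ± 0.14, 6.66-fold, edgeR adjusted p = 3.4e-08). RR9 (Os11g0143300) went from 10.9 ± 0.513 to 63.4 ± 11.5 CPM (2.54 ± 0.14, 5.81-fold, edgeR adjusted p = 3.6e-08), and RR6 (Os04g0673300) from 7.9 ± 2.51 to 35.5 ± 5.16 CPM (2.16 ± 0.16, 4.47-fold, edgeR adjusted p = 3.5e-06). RR4 (1.85-fold, edgeR adjusted p = 8.4e-04) and RR2 (1.8-fold, edgeR adjusted p = 0.026) were also higher. RR9 and RR10 are close copies whose reads may have been divided between them, and their sum differed by 2.64 ± 0.14. Of 8 tested list members 5 rose, or 6 adjusted over the list alone, with a median of 0.87 (camera adjusted p = 1.0e-48, and adjusted p = 8.0e-05 with an estimated correlation).

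CKX4 (Os01g0940000), one of the cytokinin oxidases that degrade the hormone, rose 3.16-fold from 2.68 ± 0.305 to 8.47 ± 1.36 CPM (1.66 ± 0.29, edgeR adjusted p = 0.019). CKX3 (1.27 ± 0.26, edgeR adjusted p = 0.055) and CKX5 (1.02 ± 0.32, edgeR adjusted p = 0.29) did not pass the test. Of 8 cytokinin oxidases 1 rose, or 4 adjusted over the list alone, with a median of 0.80 (camera adjusted p = 3.1e-04, but adjusted p = 0.14 with an estimated correlation). No member of the next lists passed the test over all genes. Jasmonate genes had a median of 0.57 with 5 higher adjusted over the list alone (camera adjusted p = 1.9e-04, adjusted p = 0.46 with an estimated correlation). WRKY factors had a median of 0.48 with 6 higher (8.3e-06 and 0.22). Expansins, which loosen cell walls, had a median of -0.36 with 3 lower adjusted over the list alone (0.0022 and 0.13). Aquaporins had a median of -0.26 with none (0.0045 and 0.55), and the 3 root hair genes -1.64 with 2 lower (0.0049 and 0.21). The jasmonate list, which moved with the within-group component (0.83), lost its call without replicate 2 of every group (camera adjusted p = 0.06), and the root hair list lost its call without the 4 php libraries (0.23). The 9 diterpenoid genes were not called (median 1.57, camera adjusted p = 0.22). Their median was -0.54 without php control replicate 2, where CPS2 was at 49.3 CPM against 1.23 and 0.318 CPM in the other php control libraries.

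In total 94 genes differed between php and WT on control medium, 82 higher and 12 lower. The largest difference among genes without a name was Os07g0162450, at 120 ± 6.73 CPM in php and 0.128 ± 0.185 CPM in WT (9.88 ± 0.41, edgeR adjusted p = 1.8e-09). Os01g0315800 was lower in php, at 18.7 ± 0.684 against 155 ± 12.8 CPM (-3.05 ± 0.09, edgeR adjusted p = 8.0e-12). The count fell to 34 without WT control replicate 1, 43 without WT control replicate 2 and 42 without php control replicate 3. The calls of CKX4 and RR2 were lost without any 1 of the 3 WT control libraries or php control replicate 3, with edgeR adjusted p up to 0.13 and 0.14. The count was 319 by DESeq2, 27 against a fold minimum of 1.5 and 33 without the 4 php libraries (CKX4 and RR2 then had adjusted p of 0.18 and 0.15). It was 17 when only these 2 groups were fitted, where RR6, RR4, RR2 and CKX4 were not called.

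**Figure D1:**
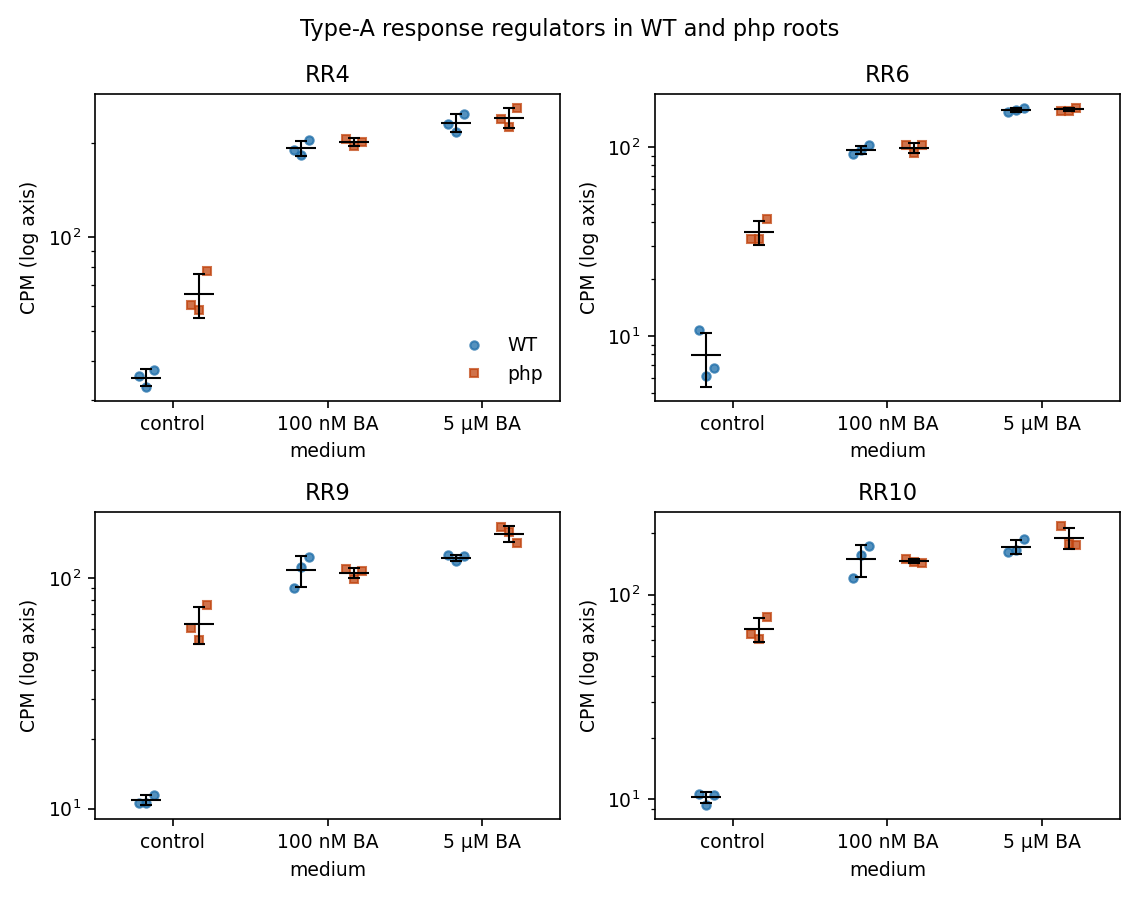
Levels of the type-A response regulators RR4, RR6, RR9 and RR10 in CPM, on a log axis, for each library (points) of WT and php on control medium and with 100 nM or 5 µM BA, with the group mean and SD. On control medium RR10 averages 10.2 CPM in WT and 67.7 CPM in php, while with 100 nM BA it averages 149 and 146 CPM.

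With BA present, the genotypes were compared again for the difference in cytokinin response genes. With 100 nM BA the type-A regulator RR10 was at 149 ± 26.5 CPM in WT and 146 ± 3.03 CPM in php, and RR6 at 96.6 ± 5.19 and 99.2 ± 5.72 CPM. None of the 8 was called (the list held a median of 0.05). In total 22 genes differed (17 higher and 5 lower in php), and 1631 reached an unadjusted p under 0.05. Photosynthesis genes had a median of 0.30 (camera adjusted p = 1.7e-05, adjusted p = 0.71 with an estimated correlation), cytokinin oxidases -0.30 (0.041 and 0.46) and WRKY factors -0.26 (0.048 and 0.71). No member of these 3 lists was called by edgeR. The cytokinin oxidase call was lost without replicate 2 (0.051) or 3 (0.21) of every group, and the WRKY call without replicate 3 (0.77).

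With 5 µM BA, 116 genes differed, 92 higher and 24 lower in php, and neither a type-A regulator nor a cytokinin oxidase was among them. The type-A list had a median of 0.11 with 1 higher adjusted over the list alone (camera adjusted p = 0.14). This was RR2, at 319 ± 27 CPM in WT and 461 ± 61.7 CPM in php (0.53 ± 0.15, edgeR adjusted p = 0.18, DESeq2 adjusted p = 0.044). Cytokinin oxidases had a median of 0.26 with 1 higher over the list alone (camera adjusted p = 0.44), CKX3, at 59.9 ± 13.6 and 109 ± 32 CPM (0.86 ± 0.26, edgeR adjusted p = 0.18). Both genes were picked out after their values were seen. GA3OX2 (Os01g0177400), an enzyme of gibberellin synthesis, was at 25.3 ± 6.4 CPM in php and 5.53 ± 1.36 CPM in WT (2.19 ± 0.40, 4.58-fold, edgeR adjusted p = 0.022). The plasma membrane aquaporins PIP2-5 (1.95 ± 0.39, 3.87-fold, edgeR adjusted p = 0.042) and PIP2-4 (0.88 ± 0.18, 1.84-fold, edgeR adjusted p = 0.042) were higher in php. Photosynthesis genes had a median of 0.47 with 4 higher adjusted over the list alone (camera adjusted p = 1.2e-05, adjusted p = 0.71 with an estimated correlation). WRKY factors had a median of -0.59 with 4 lower (5.4e-04 and 0.42), and jasmonate genes -0.35 with none (4.1e-04 and 0.5). Diterpenoid genes had a median of -1.37 with none (0.0092 and 0.71), and chitinases and pathogenesis-related proteins -0.56 with none (0.039 and 0.68). The 4 lists other than WRKY were among those closest to the within-group component. The count fell to 43, 40, 66 and 73 without WT replicate 2, WT replicate 3, php replicate 1 and php replicate 2 of this medium. The calls of GA3OX2, PIP2-4 and PIP2-5 were each lost without those 4 libraries in turn (PIP2-5 also without php replicate 3 or the 4 php libraries), with edgeR adjusted p up to 0.17, 0.27 and 0.21. DESeq2 called 551 genes with a different balance, 351 higher and 200 lower, and the fit of these 2 groups called 16. With the replicate number as a block the calls split almost evenly between higher and lower, as given below. Leaving out replicate 2 of every group ended the photosynthesis call (0.054), replicate 3 the diterpenoid call (0.12), and replicate 1 (0.057) or 3 (0.097) the call of the pathogenesis-related list.

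The response of WT roots to 100 nM BA asks which genes the hormone moves in the reference genotype. CKX2 (Os01g0197700) went from 0, 2 and 4 counts in the control libraries to 20 ± 0.741 CPM (7.50 ± 0.53, 182-fold, edgeR adjusted p = 1.6e-06). With so few control counts this value was 6.85 without WT control replicate 1 and 8.49 without replicate 3. RR10 rose 14.7-fold (3.88 ± 0.15, edgeR adjusted p = 1.0e-09), RR6 12.2-fold (3.60 ± 0.17), RR9 9.9-fold (3.31 ± 0.14) and RR4 5.44-fold (2.44 ± 0.12). Type-A regulators had 6 of 8 members higher, also when adjusted over the list alone, and a median of 2.44 (camera adjusted p = 2.9e-140, adjusted p = 1.1e-06 with an estimated correlation). Of the cytokinin oxidases 6 of 8 rose by either adjustment, with CKX5 at 2.88 ± 0.32 and CKX4 at 2.85 ± 0.29 and a median of 1.53 (1.7e-31 and 1.0e-04). ACO3, which makes ethylene from its precursor, rose 8.36-fold (3.06 ± 0.27), and ACS1, which makes that precursor, rose by 1.47 ± 0.28.

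The nitrogen list fell, with 4 of 13 members lower, or 9 adjusted over the list alone, and a median of -1.38 (camera adjusted p = 5.4e-13, adjusted p = 0.04 with an estimated correlation). Its lower members included the ammonium transporters AMT1.3 (-2.89 ± 0.54) and AMT1.1 (-1.61 ± 0.28) and the nitrate transporter NRT1.1B, which went from 69.5 ± 9.88 to 19.1 ± 1.36 CPM (-1.86 ± 0.22, edgeR adjusted p = 2.7e-04). Aquaporins had 6 of 18 lower, or 8 adjusted over the list alone, with a median of -0.53 (3.1e-10 and 0.1). PIP2-5 was at -2.62 ± 0.39 and PIP2-4 at -1.27 ± 0.18. Also lower were GA2OX1, which inactivates gibberellins (-3.26 ± 0.34), and the small heat shock protein HSP23.2 (-2.16 ± 0.49, edgeR adjusted p = 0.027). So were IPT4, a cytokinin synthesis enzyme (-1.89 ± 0.35), and CRL1, a transcription factor needed for crown root initiation (-1.78 ± 0.34). Among receptors, HK4 rose (1.03 ± 0.12) and HK3 fell (-1.05 ± 0.12), and the type-B regulator RR26, of the class that switches on cytokinin targets, fell (-1.12 ± 0.15). LOGL6, of the family that releases active cytokinin, rose (1.63 ± 0.28), as did the auxin repressor gene IAA23 (1.02 ± 0.17). The iron list had no member called over all genes and 2 lower adjusted over the list alone (median -1.14, camera adjusted p = 1.9e-04, adjusted p = 0.5 with an estimated correlation). WRKY factors had 1 and 3 higher (median 0.54, 0.0037 and 0.54). Ethylene synthesis had 2 of 7 higher, with 1 more lower over the list alone (median 0.16, 0.014 and 0.39). Gibberellin oxidases had 1 of 8 higher and 2 lower by either adjustment (median -0.67, 0.0035 and 0.059).

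In total 660 genes changed, 371 higher and 289 lower. The count was 370, 427 and 414 without WT control replicate 1, 2 and 3 and 439 without replicate 1 of the BA group. Single libraries also ended the calls of AMT1.3 (without BA replicate 1, edgeR adjusted p = 0.051), ACS1 (without WT control replicate 1 or 2, up to 0.057) and HSP23.2 (without WT control replicate 1 or 3 or any BA library, up to 0.15). Leaving out replicate 1 of every group ended the calls of iron uptake (0.052) and ethylene synthesis (0.11) and replicate 3 that of WRKY factors (0.18). Gibberellin oxidases turned with a stricter filter (0.49), and the total was 1092 without the 4 php libraries.

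With 5 µM BA, 1341 genes changed in WT, 757 higher and 584 lower. CKX2 reached 89.2 ± 22.5 CPM (9.66 ± 0.52, 811-fold, edgeR adjusted p = 3.0e-08, but 9.0 without WT control replicate 1 and 10.64 without replicate 3). RR6 reached 157 ± 4.04 CPM (4.31 ± 0.18, 19.8-fold), RR10 171 ± 13.6 CPM (4.07 ± 0.15, 16.8-fold) and RR9 122 ± 3.87 CPM (3.49 ± 0.14, 11.2-fold). ACO3 (3.48 ± 0.28), CKX5 (3.45 ± 0.33), CKX4 (3.22 ± 0.29) and ACS1 (2.60 ± 0.29) rose. Type-A regulators had 6 of 8 members higher, or 7 adjusted over the list alone (median 2.86, camera adjusted p = 2.1e-120, adjusted p = 1.9e-06 with an estimated correlation). Cytokinin oxidases had 5 of 8 higher, or 7 (median 1.78, 6.6e-29 and 1.3e-04). WRKY transcription factors, many of which act in defence, had 6 of 13 higher, or 8 with 1 lower over the list alone (median 0.90, 4.2e-08 and 0.14). They included WRKY28 (3.44 ± 0.61, edgeR adjusted p = 0.0027), WRKY24 (1.69 ± 0.27) and WRKY70 (1.45 ± 0.19). Jasmonate genes had 5 of 11 higher, or 7 (median 1.09, 3.9e-08 and 0.19). Among them were the signalling repressors TIFY11D (2.26 ± 0.48) and TIFY10B (1.22 ± 0.20) and the synthesis enzyme AOS1 (0.73 ± 0.16). Ethylene synthesis had 2 of 7 higher by either adjustment (median 0.31, 1.6e-04 and 0.14).

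The nitrogen list had 5 of 13 members lower with 5 µM BA, or 8 adjusted over the list alone (median -1.24, camera adjusted p = 6.7e-11, adjusted p = 0.063 with an estimated correlation). AMT1.3 was at -2.73 ± 0.54, NRT1.1B at -2.04 ± 0.23 and the nitrite reductase NIR1 at -0.95 ± 0.13. Aquaporins had 6 of 18 lower, or 7 with 1 higher over the list alone (median -0.40, 5.0e-08 and 0.15), including PIP2-5 (-3.10 ± 0.40), PIP2-4 (-1.55 ± 0.18) and the silicon channel NIP2-1 (-1.32 ± 0.20). HSP23.2 (-3.29 ± 0.52), the auxin transporter PIN5B (-3.12 ± 0.86, edgeR adjusted p = 0.049), GA2OX1 (-2.83 ± 0.33) and IPT4 (-1.95 ± 0.35) also fell. Without BA replicate 1 PIN5B was at -4.84 and IPT4 at -2.57. HK3 (-1.37 ± 0.12) and RR26 (-1.45 ± 0.15) fell. HK4 (1.25 ± 0.12), LOGL6 (1.83 ± 0.28), GA20OX1, a gibberellin synthesis enzyme (1.11 ± 0.21), and IAA23 (1.35 ± 0.17) rose. Iron uptake had 1 of 8 lower, or 2 (median -1.16, 0.0024 and 0.64), and photosynthesis 1 of 24 lower by either adjustment (median -0.37, 0.0029 and 0.83). The total was 861 without WT control replicate 1, 807 and 849 without BA replicates 2 and 3, and 2165 in the fit of these 2 groups. Single libraries ended the calls of PIN5B (any WT control library or BA replicate 2 or 3, edgeR adjusted p up to 0.21), TIFY11D (WT control replicate 3 or BA replicate 2, up to 0.056) and AOS1 (WT control replicate 1 or 2 or BA replicate 2, up to 0.065).

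The same treatments were tested in php. With 100 nM BA, CKX2 went from 1, 3 and 7 counts to 11.2 ± 1.53 CPM (5.83 ± 0.49, 56.8-fold, edgeR adjusted p = 3.8e-05, but 6.81 without php control replicate 3 and 7.53 without the 4 php libraries). ACO3 (3.12 ± 0.27), the type-A regulators RR1 (2.19 ± 0.20), RR4 (1.62 ± 0.11), RR2 (1.53 ± 0.16), RR6 (1.48 ± 0.16) and RR10 (1.11 ± 0.13), and CKX5 (1.89 ± 0.31) rose. Type-A regulators had 6 of 8 higher, or 7 adjusted over the list alone (median 1.5, camera adjusted p = 4.1e-50, adjusted p = 4.9e-05 with an estimated correlation). Cytokinin oxidases had 2 of 8 higher, or 4 (median 0.74, 6.4e-13 and 0.0032). The nitrogen list had 3 of 13 lower, or 9 (median -1.61, 1.1e-13 and 0.034), with AMT1.1 at -1.83 ± 0.29 and NRT1.1B at -1.61 ± 0.22. HK3 (-1.07 ± 0.12), IAA6 (-1.17 ± 0.20) and PIP2-5 (-2.02 ± 0.38) fell and HK4 rose (0.92 ± 0.12). Aquaporins had 4 of 18 lower, or 5 with 1 higher (median -0.40, 1.0e-06 and 0.19), and WRKY factors had 1 of 13 lower, or 2 (median -0.28, 0.0023 and 0.5). Ethylene synthesis had 1 of 7 higher, or 2 with 1 lower (median 0.51, 8.1e-04 and 0.17), and gibberellin oxidases had 1 of 8 lower, or 3 with 1 higher (median -0.65, 0.046 and 0.18). With no member called over all genes, expansins had 4 higher over the list alone (median 0.21, 0.01 and 0.19). With none by either adjustment, the medians were -0.93 for iron uptake (0.0054 and 0.69), -2.80 for diterpenoid genes (0.006 and 0.71, but -0.15 without php control replicate 2) and 0.22 for photosynthesis (0.037 and 0.89). In total 389 genes changed (177 higher and 212 lower), against 79 in the fit of these 2 groups. Without php control replicate 1 or BA replicate 1, 2 or 3 the count was 157, 240, 229 or 165, and the call of PIP2-5 was lost in all of these but the second (edgeR adjusted p up to 0.083). Without the 4 php libraries the count was 123, without CKX5 (0.058), IAA6 (0.068) and PIP2-5 (0.064), and the calls of the diterpenoid (0.6), iron (0.25), WRKY (0.19) and gibberellin (0.15) lists ended. Leaving out 1 replicate of every group ended the calls of photosynthesis (replicate 1, 0.11, and 2, 0.067), gibberellin oxidases (replicate 1, 0.05, and 2, 0.15) and expansins (replicate 1, 0.095).

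With 5 µM BA, 976 genes changed in php, 516 higher and 460 lower. CKX2 reached 74.3 ± 27.4 CPM (8.56 ± 0.49, 376-fold, edgeR adjusted p = 2.9e-07, but 9.54 without php control replicate 3 and 10.01 without the 4 php libraries). ACO3 (3.22 ± 0.27), CKX5 (2.72 ± 0.31), ACS1 (2.62 ± 0.29) and GA3OX2 (2.31 ± 0.40) rose. RR1 (2.69 ± 0.20), RR6 (2.15 ± 0.16), RR2 (1.89 ± 0.16), RR4 (1.88 ± 0.11) and CKX4 (1.78 ± 0.27) also rose. Type-A regulators had 6 of 8 higher, or 7 adjusted over the list alone (median 1.88, camera adjusted p = 3.4e-61, adjusted p = 2.0e-05 with an estimated correlation). Cytokinin oxidases had 5 of 8 higher, or 6 (median 1.5, 6.6e-26 and 1.3e-04). Expansins had 4 of 14 higher, or 5 (median 0.29, 6.1e-04 and 0.096), among them EXPA2 (1.32 ± 0.25) and EXPA5 (0.85 ± 0.15). NRT1.1B (-1.87 ± 0.23), AMT1.1 (-1.51 ± 0.28), HK3 (-1.40 ± 0.12), IAA6 (-1.35 ± 0.20), GA2OX1 (-2.67 ± 0.34), LOGL10 (-1.85 ± 0.33), RR26 (-0.93 ± 0.15) and NIP2-1 (-1.21 ± 0.20) fell. HK4 (1.18 ± 0.12), GA20OX1 (1.44 ± 0.21) and IAA23 (1.5 ± 0.17) rose. The nitrogen list had 4 of 13 lower, or 6 (median -1.39, 2.0e-09 and 0.077), and aquaporins 1 of 18 lower, or 2 with 1 higher (median -0.23, 0.038 and 0.71). Ethylene synthesis had 2 of 7 higher and 1 lower by either adjustment (median 0.04, 0.002 and 0.19). Neither jasmonate genes nor WRKY factors were called as lists (1 WRKY factor, WRKY13, fell by 0.76 ± 0.13). PHP3 rose (0.40 ± 0.10, edgeR adjusted p = 0.047), a call lost without php control replicate 1 or 2 or BA replicate 1 or 3 (up to 0.15). The total was 557 without php control replicate 1, 597 without BA replicate 1, 630 without the 4 php libraries (where GA3OX2, CKX4 and EXPA5 were not called, with adjusted p of 0.14, 0.054 and 0.054) and 166 in the fit of these 2 groups. The aquaporin call ended without replicate 3 of every group (0.85) or the 4 php libraries (0.73).

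Both doses were then compared within each genotype. In WT, 5 genes were higher with 5 µM than with 100 nM BA and none was lower, with 989 at an unadjusted p under 0.05. CKX2 was one of them (2.16 ± 0.31, 4.47-fold, edgeR adjusted p = 0.026). As lists and with no other member called, jasmonate genes had a median of 0.65 with 3 higher adjusted over the list alone (camera adjusted p = 6.7e-11, adjusted p = 0.13 with an estimated correlation), and WRKY factors 0.52 with 4 higher (1.3e-07 and 0.15). Photosynthesis had a median of -0.39 with 2 lower (1.3e-10 and 0.5), cytokinin oxidases 0.29 with 1 higher (2.7e-04 and 0.13), type-A regulators 0.23 with 2 higher (1.5e-05 and 0.14) and ethylene synthesis 0.41 with 2 higher (0.0022 and 0.21). Diterpenoid genes had a median of 1.58 (7.5e-05 and 0.52), expansins 0.24 (0.044 and 0.34) and gibberellin oxidases 0.25 (0.035 and 0.15), with no member called by either adjustment. The CKX2 call was lost without any of the 3 libraries with 100 nM BA or replicate 2 or 3 with 5 µM BA (edgeR adjusted p up to 0.23), where the count was 2 or 3. DESeq2 called 56 genes, and the fit without the 4 php libraries 8. Leaving out replicate 2 of every group ended the list calls of expansins (0.23), ethylene synthesis (0.063) and gibberellin oxidases (0.1), and replicate 3 those of expansins (0.24) and gibberellin oxidases (0.17).

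In php, 58 genes differed between the doses, 39 higher and 19 lower with 5 µM BA. CKX2 (2.73 ± 0.32, 6.62-fold, edgeR adjusted p = 0.0014), GA3OX2 (2.47 ± 0.40, 5.53-fold, edgeR adjusted p = 0.017) and ACS1 (1.61 ± 0.28, 3.05-fold, edgeR adjusted p = 0.022) were higher with the larger dose. Cytokinin oxidases had 1 of 8 higher, or 4 adjusted over the list alone (median 0.85, camera adjusted p = 2.7e-14, adjusted p = 0.0024 with an estimated correlation), and gibberellin oxidases 1 of 8, or 3 with 1 lower (median 0.52, 6.4e-04 and 0.034). With no member called, type-A regulators had 6 higher adjusted over the list alone (median 0.44, 1.2e-08 and 0.052), aquaporins 1 (median 0.24, 0.011 and 0.63) and photosynthesis none (median -0.29, 4.1e-05 and 0.71). The count was 37, 14 and 25 without replicate 1, 2 and 3 with 100 nM BA and 21 and 16 without replicate 1 and 2 with 5 µM BA. The calls of GA3OX2 (100 nM replicate 2 or 3 or 5 µM replicate 1 or 2, edgeR adjusted p up to 0.13) and ACS1 (any 100 nM library or 5 µM replicate 2 or 3, up to 0.16) were lost. Replicate numbers paired these libraries, and with the number as a block 164 genes were called, including those 58, while the fit of these 2 groups called 1 and the fold minimum left 7. The list calls of aquaporins (without replicate 2, 0.48) and photosynthesis (without replicate 3, 0.24) ended.

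The genotype by BA interaction tests whether the response to BA differed between php and WT. With 100 nM BA, 6 genes had a negative interaction and none a positive one, with 756 at an unadjusted p under 0.05. RR10 (-2.77 ± 0.19), RR9 (-2.58 ± 0.18) and RR6 (-2.12 ± 0.22) were among them, with edgeR adjusted p of 4.5e-06, 4.5e-06 and 5.9e-04 and a call in each of 12 fits that left out 1 library. The sum of RR9 and RR10 differed between genotypes by 2.64 on control medium and by -0.04 with 100 nM BA. Its interaction of -2.68 is thus the difference on control medium seen again, and not a separate finding. Of 8 type-A regulators 3 were called, or 5 adjusted over the list alone (median -0.77, camera adjusted p = 1.6e-55, adjusted p = 4.9e-05 with an estimated correlation). With no member called over all genes, cytokinin oxidases had 2 lower adjusted over the list alone (median -1.03, 1.3e-09 and 0.015), WRKY factors 6 (median -0.78, 9.4e-13 and 0.054) and jasmonate genes none (median -0.42, 5.4e-05 and 0.4). The count was 3 without php replicate 2 with 100 nM BA and 47 by DESeq2.

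With 5 µM BA, 112 genes had an interaction, 40 positive and 72 negative. RR10 (-2.59 ± 0.19, edgeR adjusted p = 1.6e-05), RR9 (-2.20 ± 0.18, edgeR adjusted p = 2.8e-05) and RR6 (-2.15 ± 0.22, edgeR adjusted p = 3.6e-04) were called in each of 12 fits that left out 1 library. The sum of RR9 and RR10 differed between genotypes by 0.23 ± 0.13 with 5 µM BA, against 2.64 ± 0.14 on control medium. Most of its interaction is again the difference on control medium. WRKY71 (-2.33 ± 0.43, edgeR adjusted p = 0.027), WRKY70 (-1.38 ± 0.27, edgeR adjusted p = 0.034), RR4 (-0.83 ± 0.16, edgeR adjusted p = 0.027) and PIP2-4 (1.32 ± 0.25, edgeR adjusted p = 0.03) were called. WRKY24 (-1.49 ± 0.37, edgeR adjusted p = 0.14) and PIP2-5 (2.21 ± 0.53, edgeR adjusted p = 0.12) were not. WRKY71 was at 15.2 ± 3.35 CPM in WT control and 44.4 ± 10.6 CPM in WT with 5 µM BA, and at 42.6 ± 19.4 and 24.8 ± 6.6 CPM in php. WRKY factors had 2 of 13 members lower, or 7 adjusted over the list alone (median -1.04, camera adjusted p = 2.7e-14, adjusted p = 0.04 with an estimated correlation). Type-A regulators had 4 of 8 lower by either adjustment (median -0.58, 2.9e-31 and 4.4e-04). Jasmonate genes had none called and 8 lower adjusted over the list alone (median -0.88, 1.9e-12 and 0.096), and aquaporins 1 of 18 higher, or 2 (median 0.32, 2.9e-04 and 0.41). The count was 50, 62 and 63 without WT control replicate 1, 2 and 3, 48 and 45 without WT replicate 2 and 3 with 5 µM BA, 71 without php control replicate 3 and 55 without php replicate 1 with 5 µM BA. Of the 12 such fits 6 called WRKY71 (adjusted p up to 0.086), 3 called RR4 (up to 0.11), and 2 each called WRKY70 (up to 0.12) and PIP2-4 (up to 0.11). Without the 4 php libraries 28 genes were called, 15 positive and 13 negative, and WRKY71 (-1.62, adjusted p = 0.31), WRKY70 (0.16), RR4 (0.089) and PIP2-4 (0.11) were not among them. The excess of negative calls was also absent in the fit of these 4 groups (23 positive and 25 negative) and against the fold minimum (13 and 11).

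**Figure D2:**
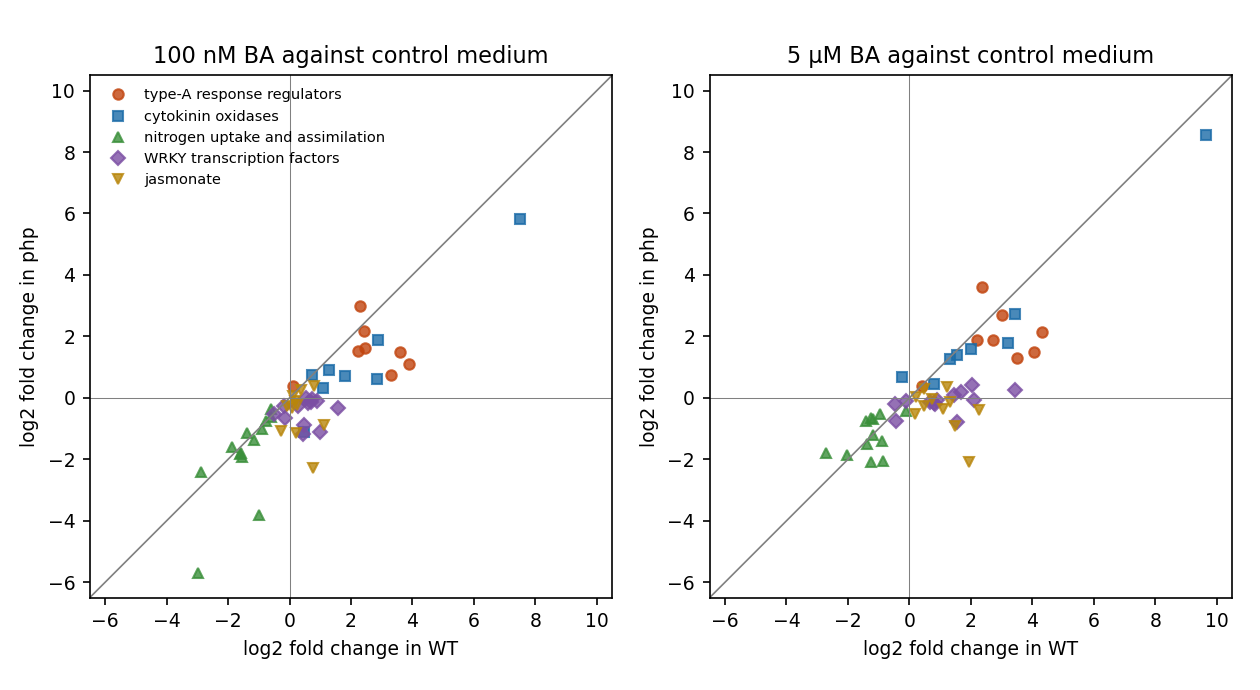
Log2 fold change with BA against control in WT (horizontal axis) and in php (vertical axis) at 100 nM and 5 µM, 1 point per tested member of the type-A response regulator, cytokinin oxidase, nitrogen, jasmonate and WRKY lists, with the line of equal response. The type-A regulators RR6, RR9 and RR10 lie below the line, with interactions of -2.15, -2.20 and -2.59 at 5 µM.

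The genotype difference on control medium was also set against the BA responses. Of the 94 genes, 54 also changed with BA in WT in the same direction (50 higher and 4 lower) and 3 in the opposite one, among 1401 genes that BA changed in WT at either dose. The 82 genes higher in php shared 43 with the 371 raised by 100 nM BA in WT, where independent lists would share 1.1, and 45 with the 757 raised by 5 µM BA, where they would share 2.2. In 20 simulations of unchanged groups sharing the controls, the top lists of these sizes shared a mean of 30.8 (up to 36) and 42 (up to 51). The observed 43 lay above the highest simulated value for its dose, and the 45 lay below its own. No simulation shared a called gene, but unchanged groups are rarely called at all, so this is no measure for the 43 and 45. The 12 lower genes shared 4 with each dose, where independent lists would share 0.13 and 0.25 and simulated top lists 3.9 (up to 7) and 5.25 (up to 9). Both comparisons use the WT control libraries, and with 3 of these no split left 2 in each part, so part of the excess may come from them. Against the BA responses of php, which share the php control libraries instead, 8 of the 94 genes moved the same way and 3 the opposite way with 100 nM BA, and 10 and 16 with 5 µM BA. RR2, RR4, RR6, RR9 and RR10 moved the same way in both. Across the 27607 tested genes, which are not independent replicates, the difference correlated with the response to 5 µM BA in WT at r = 0.36 (Spearman 0.25), with a covariance of 0.147 against 0.123 (0.111 to 0.132) simulated for unchanged groups sharing the controls, a difference of 0.0235. For 100 nM BA r was 0.40 (Spearman 0.39), and the covariance 0.144 against 0.123 (0.109 to 0.136), a difference of 0.0209. The simulated groups gave a mean r of 0.50 at each dose, so the observed r values do not exceed what shared controls alone can give. With the dose comparisons, which share no library with it, r was 0.01 in WT (Spearman -0.15), with a covariance of 0.00304 against a simulated range of -0.00946 to 0.012. In php r was -0.06 (Spearman -0.06), with a covariance of -0.018, below the simulated range of -0.0108 to 0.0104, and r was -0.61 over the 58 genes called in that dose comparison. The simulations drew each gene independently and held no within-group component. Their ranges are therefore no bounds for what unchanged groups could give, and a covariance or overlap outside them decides nothing.

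Of the 94 genes 21 also differed the same way in both BA media, 16 higher and 5 lower in php, and 62 differed in neither. Of the 21, 1 also changed with BA in WT in that direction, and 6 had at most 3 counts over the 9 WT libraries together.

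The size of the BA response was compared over genes called in either genotype. The slope of php on WT was 0.58 over 777 genes with 100 nM BA (r = 0.78 across genes, 94.3% with the same sign) and 0.57 over 1762 genes with 5 µM BA (r = 0.67, 85.8%). These genes were chosen on the same data, and the slope with 5 µM BA ranged from 0.29 over genes called in WT alone to 1.53 over genes called in php alone. WT and php shared 124 genes raised and 148 lowered by 100 nM BA, where independent lists would share 2.4 and 2.2, and 298 and 245 with 5 µM BA (14 and 9.7), in comparisons without a common library. Within WT the 2 doses shared 333 raised and 267 lowered genes (independent lists 10 and 6.1), and within php 153 and 156 (3.3 and 3.5), each pair of comparisons sharing its control libraries. Top lists of these sizes in 20 simulations without effect, which drew each gene independently, shared a mean of 125 raised and 60.1 lowered (up to 144 and 74) in WT and 64.7 and 42.8 (up to 76 and 53) in php. No call was shared there, but simulations without effect rarely call a gene.

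Several lists held changed members, some of them more than 1, without a call of the list in any of the 11 comparisons. Type-B response regulators (lowest camera adjusted p = 0.25), cytokinin receptors and phosphotransfer proteins (0.28), cytokinin synthesis (0.058), Aux/IAA proteins (0.14), auxin transport (0.37), circadian clock (0.25), crown root and meristem regulators (0.25) and heat shock proteins (0.12) were of this kind. Cell cycle and histone genes had neither (0.32). The PHP list was called with 100 nM BA (median 0.13, 0.013, adjusted p = 0.34 with an estimated correlation), a call lost without replicate 1 of every group (0.11).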

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

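Of the tests in this part, the one on the component that separates libraries within groups was chosen before its result was seen, and all others, the regroupings of libraries included, were chosen after it.

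The results below were picked out because the response to BA differed between php and WT by a test of the difference itself. With 100 nM BA 6 genes and with 5 µM BA 112 genes had an interaction. At 100 nM the named ones were RR10 (-2.77), RR9 (-2.58) and RR6 (-2.12). At 5 µM they were RR10 (-2.59), WRKY71 (-2.33), RR9 (-2.20), RR6 (-2.15), WRKY70 (-1.38), RR4 (-0.83) and PIP2-4 (1.32). No type-A regulator was called between genotypes with either BA dose. The interactions of these regulators mostly restate the difference on control medium, and do not separate a starting level from a response.

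Among lists with 100 nM BA, the median interaction was -0.77 for type-A regulators, -1.03 for cytokinin oxidases, -0.78 for WRKY factors, -0.42 for jasmonate genes, -1.83 for diterpenoid genes and 0.17 for expansins. With estimated correlations the adjusted p was 0.054 for WRKY factors, 0.4 for jasmonate genes, 0.71 for diterpenoid genes and 0.22 for expansins, so that these calls were lost. With 5 µM BA the median interaction was -0.58 for type-A regulators, -0.38 for cytokinin oxidases, -1.04 for WRKY factors, -0.88 for jasmonate genes, -3.57 for diterpenoid genes, -0.69 for chitinases and pathogenesis-related proteins, 0.20 for photosynthesis and 0.32 for aquaporins. With estimated correlations 6 of these calls were lost, with an adjusted p of 0.46 for cytokinin oxidases, 0.096 for jasmonate genes, 0.52 for diterpenoid genes, 0.55 for pathogenesis-related proteins, 0.87 for photosynthesis and 0.41 for aquaporins. The diterpenoid medians rest largely on php control replicate 2, without which they were 0.03 with 100 nM and -0.88 with 5 µM BA, and the list's calls were lost without the 4 php libraries (camera adjusted p = 0.93 and 0.15).

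Regroupings of the libraries were counted in fits of the compared groups alone. For the 5 µM interaction 2 of 60 regroupings gave as many genes, the real one (48) included, a share under 0.05, and the other gave 122. For the 100 nM interaction 5 of 60 gave as many, with 4 genes in the real grouping and 69 in the highest other. In both cases the highest other exchanged the genotype labels in the BA medium, which tests the genotype difference common to both media. Regroupings that carry this difference do not stand for an absent interaction. Chance was therefore not excluded for either dose.

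For comparisons of 2 groups 10 splits are too few for a share under 0.05. The real split and the highest other gave 17 and 1 genes for php against WT on control medium, 12 and 0 with 100 nM BA and 16 and 0 with 5 µM BA. In WT they gave 593 and 1 with 100 nM BA, 2165 and 0 with 5 µM BA, and 4 and 3 between the doses. In php they gave 79 and 0 with 100 nM BA, 166 and 285 with 5 µM BA, and 1 and 0 between the doses. The split with 285 genes set php control replicates 1 and 3 and php replicate 3 with 5 µM BA against the rest, which follows the component within groups.

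The higher level of type-A regulators in php on control medium was weighed first. Without any scaling factors the list median minus the median of all genes was 0.86, and the 3 php control libraries, at both ends and in the middle of the within-group component, had list medians of 0.78, 0.67 and 1.13 above the WT control mean, against at most 0.06 in a WT control library, which argues against scaling or the libraries at the ends as the cause. RNA of BA-treated roots in the php control libraries would bring other BA-raised genes to the same share of their BA level. Over 118 such genes the upper quartile of that share was 19.1%, with 0.861% for CKX2 and 0.779% for ACO3. RR6, RR9 and RR10, the 3 type-A members with the largest difference, stood at 30.3%, 55.9% and 42.5%. The 118 genes had to rise above php control, which leaves out genes already near their BA level there. Other type-A members were not compared with them. RR2 was at 69.1 CPM in WT control, 124 in php control and 359 in php with 100 nM BA, and RR4 at 35.4, 65.7 and 202. ACO3, at 29 ± 6.07 CPM in WT control, 30.9 ± 9.73 in php control and 269 ± 5.91 in php with 100 nM BA, goes against such RNA. So does CKX2, which had few counts without BA. The share differed widely among the 118 genes, however, with an upper quartile of 19.1%. For RR2 and RR4 such RNA was therefore not decided. A candidate explanation, as a hypothesis found and tested on these data, is that the genotype itself raised RR6, RR9 and RR10 without added hormone.

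A second pattern is the 21 genes that differed between php and WT in all 3 media, 6 of them with at most 3 counts over all 9 WT libraries. A single linked chromosome segment would place most of them together. Of the 21, 4 lay within 50 tested genes of another, which is the 95th percentile (4) of 10000 random draws, and 0 lay that close to a PHP gene. The 21 genes spread over 8 chromosomes, which argues against 1 segment that holds most of them. Several segments, or genes further apart within a segment, could pass unseen by this test and stay open. Reads moved between near-identical genes stay open, since no transcript sequences were used here, and 2 of the 21 genes had identical values. A difference of sequence or insertions between the lines may also give such genes and was not tested.

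The third pattern is the set of 24 jasmonate and WRKY genes, whose median change with 5 µM BA was 0.99 in WT and -0.12 in php, an interaction of -1.01. Leaving out php control replicate 2, which lay at one end of the within-group component, left it at -0.99. The median was not taken without php replicate 3 with 5 µM BA, at the other end (-75.4). The component predicted 9.27% of the median interaction (8.66 to 9.66% leaving out 1 chromosome at a time). These values argue against php control replicate 2 or the component as the whole cause. That range reflects the choice of genes and not the spread between libraries. The median jasmonate and WRKY members correlated with the component at 0.83 and 0.55, so a part played by it stays open. On control medium these genes were higher in php than in WT by a median of 0.49, so that a different starting level and a different response may both contribute, and the design does not separate them. A difference between genotypes stays a hypothesis.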

How the results depend on the processing

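Leaving out 4 php libraries, summing RR9 and RR10 and the correlation over genes called in php were chosen after the results were seen, and the other alternatives before. Counts of genes are given in the order php against WT (control, 100 nM, 5 µM), WT with BA (100 nM, 5 µM), php with BA (100 nM, 5 µM), dose in WT and php, and interaction (100 nM, 5 µM). DESeq2's factors, no factors, no filter, the stricter filter and length offsets moved no count by over 1.5 times. The cause of the changes below was not tested. A fold minimum tests a larger change. Leaving out libraries or groups leaves fewer samples, which does not account for a count that rose. With only the compared groups fitted, WT with 5 µM BA rose from 1341 to 2165 genes, while php fell from 976 to 166. The main fit shares information on spread among all groups. The chi-square per degree of freedom reached 64.5 in php control and 61.4 in php with 5 µM BA, but 28.6 within WT groups. Whether this sharing moved the counts was not tested. DESeq2 gave 319, 81, 551, 1057, 854, 1526, 56, 230, 47 and 314 genes (WT with 5 µM BA within 1.5 times). The fold minimum gave 27, 29, 132, 385, 57, 209, 1, 7, 3 and 24 (php against WT with 100 nM BA within 1.5 times). The fit of the compared groups gave 17, 12, 16, 2165, 79, 166, 1 and 48 (WT with 100 nM, dose in WT and the 100 nM interaction within 1.5 times). Without the 4 php libraries, where php control keeps 1 library that is assumed to vary like the others, the fit gave 33, 1092, 123, 630, 8 and 28 (the other 5 counts within 1.5 times).

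With the replicate number as a block the counts were 220, 569, 1068, 707, 14, 164, 20 and 264 (3 within 1.5 times), and the 569 for php against WT with 5 µM BA split into 302 higher and 267 lower. By the rule that all 3 correlations exceed 0.1, the numbers paired the libraries of php with 100 nM and 5 µM BA alone, where 58 genes became 164. For the other groups correlations of deviations ran from -0.08 to 0.47, and 13 of 18 libraries were closest to their own number. All 15 correlations of replicate 2 were over 0.1, but 8 of 15 for replicate 3 and 2 of 15 for replicate 1, a hint from the data and not the design. Replicate 2 was also highest on the within-group component in 6 of 6 groups. The rule therefore does not exclude a structure by number in the other groups. The block changed no call of a named gene to uncalled, turned 7 of 15 uncalled named genes into calls, and ended 1 of 78 list calls.

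Leaving out 1 library moved the counts over 34 to 115, 19 to 21, 40 to 133, 370 to 447, 807 to 1057, 157 to 323, 557 to 1068, 2 to 5, 14 to 80, 3 to 8 and 45 to 117. Calls of named genes were kept in 730 of 984 such fits and lost in 254.

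Of the list calls, 17 of 78 held with an estimated correlation and 31 with fry, and 32 of 233 were lost when 1 replicate number was left out. Gibberellin oxidases turned direction with the stricter filter, without a call (camera adjusted p = 0.49 in WT and 0.96 in php with 100 nM BA). Uncalled PHP genes also turned: PHP3 with 5 µM BA was 0.03 without factors, 0.00 with the stricter filter, and 0.01, 0.05 and 0.06 without WT replicate 2 or 3 or php replicate 2 (-0.06 to 0.06 over single libraries), and PHP2 with 100 nM BA was -0.16, -0.17 and -0.17 without WT replicate 1, php replicate 3 or the 4 libraries.

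The correlation of the genotype difference with the 5 µM response of WT was 0.59 over genes called in it, 0.27 over genes of at least 5 CPM, 0.28 on plain log2 differences and 0.20 over genes called in php. With the WT dose comparison it turned to -0.08 and -0.11 over genes of at least 5 CPM and on plain differences, and with the php dose comparison it was -0.61 over genes called in that comparison, -0.13 over genes of at least 5 CPM and -0.10 on plain differences. The slope of php on WT was 0.33, 1.57 and 0.85 over genes called in WT alone, in php alone and in both with 100 nM BA, and 0.29, 1.53 and 0.84 with 5 µM BA, and leaving out 1 replicate gave 0.52 to 0.60 and 0.52 to 0.59. Depth limits genes near 3 counts, where PHP2 and CKX2 without BA lie.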

Other observations

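The correlation over genes called in php, used here, was chosen after the results were seen.

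Genes called with 5 µM BA in php share its control libraries with the genotype difference on control medium, so their selection favours the opposite sign. Of 516 genes raised in php 51.2% were also higher in php than WT on control medium (median 0.01), and of 460 lowered genes 27.2% were also lower (median 0.19).

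The type-A regulator RR1 (Os04g0442300), outside the genes called on control medium, was at 4.47 ± 1.19 CPM in WT and 6.58 ± 1.52 CPM in php there, and with BA at 24 ± 1.08 and 30 ± 4.37 CPM (100 nM) and 35.8 ± 5.08 and 42.3 ± 4.75 CPM (5 µM), each n = 3. RR3, of the same list, had group means between 1.26 and 1.79 CPM in all 6 groups, and RR7 had group means below 1 CPM. RR7 was at 0.188 ± 0.28 CPM in WT control and 0.957 ± 0.781 CPM in WT with 5 µM BA. In php it was at 0.0569 ± 0.0539 and 0.724 ± 0.348 CPM.

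Of 8 gibberellin oxidases 2 rose and 2 fell in php with 5 µM BA, and the list was not called (median 0.20, camera adjusted p = 0.72). GA20OX1 and GA3OX2, which act in synthesis, rose in php by 1.44 ± 0.21 and 2.31 ± 0.40 (edgeR adjusted p = 8.2e-04 and 0.0033), and GA2OX1, which inactivates the hormone, fell by 2.67 ± 0.34 (edgeR adjusted p = 2.5e-04). In WT GA3OX2 was at 5.87 ± 1.5 CPM on control medium and 5.53 ± 1.36 CPM with 5 µM BA, and in php at 5.1 ± 1.25 and 25.3 ± 6.4 CPM, but its interaction did not pass the test (2.39 ± 0.56, edgeR adjusted p = 0.11). DESeq2 (adjusted p = 0.0059) and the fit of the 4 groups alone (adjusted p = 0.046) called that interaction, which was looked up after the levels were seen.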
